A study of Mus musculus with 23 samples.

How the data were processed

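RNA-seq libraries were made from bone marrow-derived macrophages of wild-type mice and of mice labelled Selenow knock-out, untreated or after 4, 8 or 24 h of LPS at 100 ng/ml. The deposited values are raw counts of read pairs per gene, which the authors made with HISAT2 and featureCounts 2.0.1, per the file headers and the submitters' processing notes. Per the file headers, read pairs over exons were summed by Ensembl gene identifier with the Ensembl release 101 annotation of GRCm38. Strand was not used, a pair over several genes was counted for each of them, and reads with several alignments were not counted. The version of HISAT2 is not given, and the notes also name DESeq2, from which no deposited table was found. Total RNA was isolated with an on-column DNase step, per the labels' protocols. The table holds 55401 genes and 23 libraries. Its column of exonic length was not used. Genes were named through GENCODE mouse release 21, which gave a symbol to 55141 identifiers and none to 260. Because counting ignored strand, a gene cannot be told from its antisense partner, and genes with near-identical copies were treated as uncertain.

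Groups were taken from the labels as genotype and hours of LPS, 3 libraries each except for 2 in the labelled knock-out at 24 h. Running numbers name the replicates, and no number occurs in more than 1 group. All 23 libraries entered a single fit of 8 group means in edgeR 4.0.16 under R 4.3.3, with TMM scaling, edgeR's filterByExpr on the groups (18083 genes kept) and its quasi-likelihood F-test. Comparisons within each genotype were cells after 4, 8 or 24 h of LPS against untreated cells at 0 h, and 24 against 4 h. No untreated library is labelled with a later time, so an effect of time in culture cannot be told apart from LPS. Labelled knock-out was compared with wild-type at each time and averaged over times. The interaction of genotype and LPS was tested at each time, with a joint test of the interactions. Adjusted p-values are from the Benjamini-Hochberg method within a comparison, two-sided, and genes under 0.05 were called. Standard errors are the size of the unshrunk log2 fold change divided by the square root of F. Values per group are means with SD in TMM-scaled CPM. A gene with no reads in a group was given a bound on its fold change, with 3 counts over that group as the floor. That floor and the limit of up to 0.0769 CPM per library cover counting error only.

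A total of 42 gene lists, written before the data were examined, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation and fry were the alternatives. Members called were counted over all genes and also adjusted over the list alone. The genes named were chosen by a rule made before the data were examined. It gave Selenow, the 8 higher and 8 lower called genes with the largest fold change among those with a mean of at least 5 CPM and no overlap between the groups' libraries, up to 4 called members of any list described, and every called gene where a comparison called 5 or fewer. Interactions and the average had no overlap rule, and predicted-locus names were counted but not named. The text prints part of the genes that this rule gives, and a further gene is not reported here. Mdfi, Hist1h2an, Nr4a1, Cav1, Olfml3, Ppp1r15a and Sparc were left out of it after their calls were seen to depend on the processing. Nos2 between genotypes, and those genes of the interaction tests that the rule counts without naming, were named after their values were seen.

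Alternatives chosen before the data were examined were DESeq2 1.42.0, limma-voom, median-of-ratios (RLE) and upper-quartile scaling, no filter or a filter of at least 1 CPM in 3 libraries, an adjusted p under 0.01, a test against a fold of 1.5, a fit of only the groups compared, leaving out each library in turn, and leaving out genes within 20 Mb of Selenow. Alternatives added after seeing the data were a fit without libraries 13, 16, 19 and 22, a term for the library set at each time, and fits within each set. Library sets were found from deviations of log2 CPM from the group means over 8914 genes, and the same sets came from the odd-numbered chromosomes alone. Principal components used log2 CPM with a prior count of 2. Simulated counts with known changes were drawn from the means, spread and totals of the real libraries. They were used for LPS in wild-type cells at 4 h, the genotypes at 0 h and averaged, and the interaction at 4 h. Camera at its preset correlation was run on such counts between genotypes at 0 h. The joint test, camera with an estimated correlation and fry were not. Genes were drawn independently of each other and without library sets. Reads were not available, so alignment, strand and the deleted part of Selenow were not examined. Sex-linked genes were not used to group libraries.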

Results

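The series profiled macrophages grown from mouse bone marrow (bone marrow-derived macrophages, BMDMs) of wild-type mice and of mice labelled Selenow knock-out. Selenow encodes selenoprotein W, a small selenocysteine-containing protein. Cells were left untreated (0 h) or were given bacterial lipopolysaccharide (LPS), which macrophages sense through Toll-like receptor 4, at 100 ng/ml for 4, 8 or 24 h. The 23 RNA-seq libraries fall into 8 groups of genotype and time, with 3 libraries in each group except the labelled knock-out at 24 h, which has 2. Libraries carry running numbers from 1 to 23, used here as their replicate names. The total of counted fragments ranged from 39001456 to 41819953 per library, and from 21722 to 23575 genes had at least 1 fragment. A count of 0 in a library allows a level of up to 0.0769 CPM (counts scaled to library size), a limit that covers counting error only. The labels do not say whether libraries came from separate animals or cultures, so every p-value measures the spread between libraries only. Untreated libraries exist at 0 h only, so changes called LPS responses below include any effect of time in culture.

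Selenow itself was lower in 7 of the 11 libraries labelled knock-out and close to the wild-type level in the other 4. Untreated wild-type libraries held 127, 103 and 133 CPM of Selenow, and the labelled knock-out libraries 13, 14 and 15 held 106, 39.4 and 40.8 CPM. At 4 h the wild-type libraries held 202, 181 and 203 CPM against 191, 82.6 and 81.1 CPM in libraries 16, 17 and 18. At 8 h the wild-type libraries held 303, 319 and 327 CPM against 260, 135 and 125 CPM in libraries 19, 20 and 21. At 24 h the wild-type libraries held 169, 161 and 201 CPM against 181 and 113 CPM in libraries 22 and 23. Libraries 13, 16, 19 and 22, the first number of each labelled knock-out group, thus held 88.0%, 98.1%, 82.4% and 102% of the wild-type mean of their time. The lowest wild-type library held 85.3%. No library was free of Selenow reads, and the labels do not say which part of the gene was removed, so counts over the whole gene (GRCm38 chromosome 7, 15917208 to 15922402, minus strand) cannot show whether the remaining transcripts are intact. The log2 fold change between genotypes was -0.96 ± 0.37 (SE) at 0 h, -0.72 ± 0.37 at 4 h, -0.87 ± 0.37 at 8 h and -0.27 ± 0.41 at 24 h, with adjusted p of 0.27, 0.735, 0.288 and 0.839, so Selenow did not pass the test at any single time. The average over the 4 times was -0.70 ± 0.19, adjusted p 0.0306. Within the first library set described below, 4 of the 7 labelled knock-out libraries are 13, 16, 19 and 22, so the loss of the call there is built in (-0.43, adjusted p 0.202). The average also lost its call without library 3, 4, 12, 15, 17, 18, 20, 21 or 23 (0.0501 to 0.106). Because the targeted gene goes against the label in 4 libraries, every direction below is between libraries labelled wild-type and libraries labelled knock-out.

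**Figure D1:**
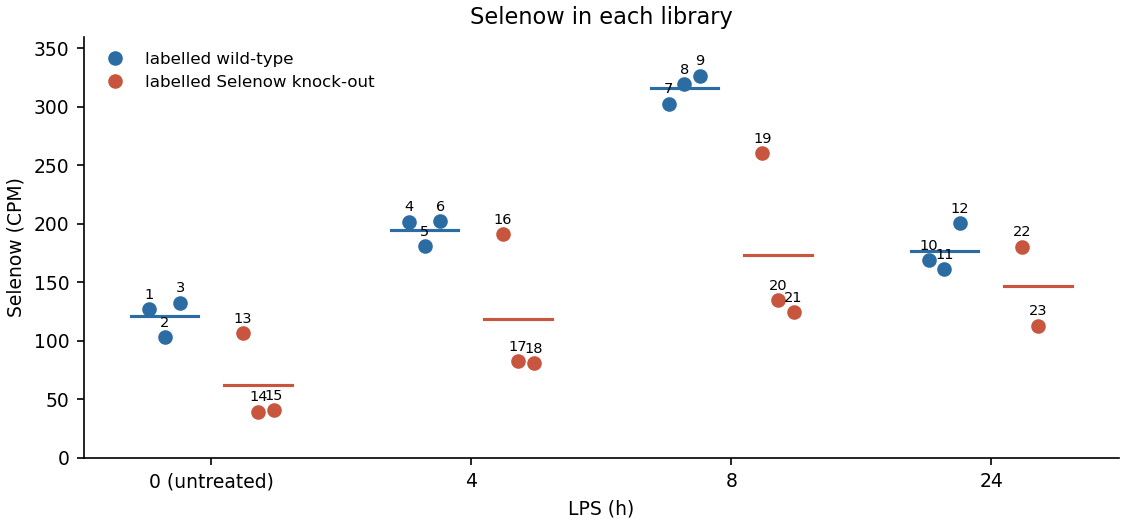
Selenow level (CPM, vertical axis) in each of the 23 libraries by hours of LPS (horizontal axis); points are libraries marked with their number, bars are group means, and colour gives the labelled genotype. Libraries 13, 16, 19 and 22 lie at 82.4% to 102% of the wild-type mean of their time, above every other labelled knock-out library of that time.

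Outside Selenow, the same 4 libraries lay nearer the other labelled knock-out libraries than the wild-type libraries. A scale ran from 0 (mean of the wild-type libraries) to 1 (mean of the other labelled knock-out libraries). It used genes with at least a 2-fold difference called between genotypes in a fit without the library in question. Libraries 13, 16, 19 and 22 had median positions of 0.942, 0.922, 0.946 and 0.803. Each fit still held the rest of the 4, which can favour a position near 1. Within each group they had the lowest share of genes nearer the labelled knock-out (82.8%, 78.2%, 78.1% and 67.5%, others 82.4% to 88.9%). For library 22, set against library 23 alone, the lower quartile was 0.317. The principal components of log2 CPM followed time before genotype. The first held 50.6% of the variance and parted untreated from treated libraries. The fourth held 4.42% and was positive in every wild-type library and negative in every labelled knock-out library. A further division ran across both genotypes. Libraries 3, 6, 9 and 12 (wild-type) and 14, 17, 20 and 23 (labelled knock-out) deviated from their group means in a shared way. The correlation across genes between the wild-type and the labelled knock-out library of this kind was 0.793, 0.791, 0.816 and 0.755 at 0, 4, 8 and 24 h on even-numbered chromosomes, after the libraries had been chosen on odd-numbered ones. Genes are not independent replicates, and choosing the best correlated pair in the same libraries favours a positive value. Below, these 8 libraries are called the second library set and the other 15 the first. The sets were found in the data and are not groups of the study, so tests that use them may give p-values that are too small.

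LPS for 4 h in wild-type cells induced the inflammatory programme of macrophages. All 20 measured inflammatory cytokine genes rose, with a median log2 fold change of 7.73. Il6 went from 0.0502 ± 0.0397 to 645 ± 333 CPM (± SD, n = 3; log2 fold change 13.57 ± 1.53, SE), Il1a changed by 12.09 ± 1.13 and Il12b by 11.90 ± 1.96. The type I interferon gene Ifnb1 had 1 read in the untreated libraries together and 34 ± 43.3 CPM at 4 h. Il33 and Il19, with no reads in any untreated wild-type library, were at least 1460-fold and 1100-fold higher, taking 3 counts over the untreated group as the floor. Of 21 chemokine genes 19 rose and none fell (median 6.63), among them Cxcl10 (10.12 ± 1.09) and Cxcl9 (9.83 ± 0.96), which encode ligands of the chemokine receptor Cxcr3. All 38 interferon-stimulated genes rose (median 4.76), among them the guanylate-binding protein gene Gbp5 (9.75 ± 0.81) and the antiviral gene Rsad2 (8.75 ± 0.77). All 24 feedback regulators of NF-kB signalling also rose (median 3.46), including Socs3 (8.64 ± 0.49), Socs1 (7.71 ± 0.40) and Tnfaip3 (7.21 ± 0.45). All 18 markers of classical activation rose (median 5.91). Nos2, the inducible nitric oxide synthase, went from 1.11 ± 1.12 to 3802 ± 937 CPM. Ptgs2 (cyclooxygenase-2) changed by 10.47 ± 0.98 and Acod1, which makes itaconate, by 9.27 ± 0.87. Edn1, the endothelin-1 gene, changed by 12.11 ± 1.03. All 14 genes of MHC class I presentation rose by a median of 1.99, with Nlrc5, the activator of these genes, at 3.52 ± 0.29. H2-Q7 and other H2-Q and H2-T genes have near-identical copies and their values are uncertain. Among the largest falls were the cannabinoid receptor gene Cnr2 (-7.31 ± 0.56), the Myc antagonist gene Mnt (-7.13 ± 0.26), the lipin gene Lpin1 (-6.80 ± 0.54), the lysophosphatidic acid receptor gene Lpar5 (-6.58 ± 0.43), Zfp395 (-7.82 ± 0.72), Frat1 (-7.25 ± 0.70), Cdca7 (-6.79 ± 0.62) and Slc26a11 (-6.60 ± 0.51). In edgeR's quasi-likelihood test 11382 of 18083 genes were called at an adjusted p under 0.05, 5092 higher and 6290 lower. Of 42 gene lists, 8 were called by camera with its preset correlation of 0.01, all higher, and only the chemokines kept their call with an estimated correlation (adjusted p = 0.00655). That value was 0.155 for the cytokines, 0.155 for the interferon-stimulated genes, 0.089 for the NF-kB regulators, 0.177 for the activation markers and 0.177 for MHC class I). When the fold had to exceed 1.5, 7384 genes were called.

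At 8 h of LPS the cytokine, chemokine and interferon genes were still high in wild-type cells, and genes of cholesterol synthesis and of cell division had fallen. Il6 stood at 112 ± 99.7 CPM and Nos2 at 2435 ± 763 CPM (n = 3). All 20 cytokine genes (median 5.77), 19 of 21 chemokine genes (median 6.87) and all 38 interferon-stimulated genes (median 5.08) were called higher than in untreated cells. The acute-phase gene Saa3 (10.79 ± 0.85), the endothelial lipase gene Lipg (11.29 ± 0.99) and Ccl5 (10.13 ± 0.65) were among the largest rises. Il23r, a subunit of the interleukin-23 receptor with no untreated reads, was at least 463-fold higher. Immediate early and handling stress genes rose in 14 of 17 cases (median 2.60), with the heat shock genes Hspa1a (9.04 ± 0.30) and Hspa1b (8.82 ± 0.30), near-identical copies whose counts are uncertain, and Fosl1 (5.69 ± 0.49). Of 20 inflammasome and cell death genes 15 rose (median 1.88), among them Zbp1 (5.13 ± 0.31) and Casp4 (4.16 ± 0.66). Antioxidant genes of the NRF2 programme rose in 15 of 24 cases, led by the cystine transporter gene Slc7a11 (5.74 ± 0.49) and the haem oxygenase gene Hmox1 (3.60 ± 0.35). Of 21 cholesterol synthesis and uptake genes 20 fell (median -2.21). Stard4 fell by -4.67 ± 0.33, Dhcr7 by -4.29 ± 0.38 and Sqle by -3.17 ± 0.36 in log2 fold change. Genes of G2 and M phase fell in 22 of 23 cases (median -2.82), with Aurkb at -3.91 ± 0.50 and Kif11 at -3.82 ± 0.43. The largest falls also included Rasgrp3 (-7.45 ± 0.57), the organic anion transporter gene Slco2b1 (-7.31 ± 0.61), St6gal1 (-6.67 ± 0.50), Tfap4 (-6.35 ± 0.57), the microglial and macrophage receptor gene Gpr34 (-6.19 ± 0.77), Abcg3 (-6.03 ± 0.68) and Deptor, an inhibitor of mTOR (-5.87 ± 0.48). Of 18083 genes 11824 were called, 5480 higher and 6344 lower, and 16 lists were called. With an estimated correlation 3 lists kept their call, the chemokines (adjusted p = 0.00833), the immediate early genes (0.00833) and the inflammasome genes (0.0392). Adjusted p was 0.136 for the cytokines, 0.0977 for the interferon-stimulated genes, 0.545 for the antioxidant genes, 0.143 for cholesterol synthesis and 0.545 for G2 and M phase. When the fold had to exceed 1.5, 7509 genes were called.

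At 24 h of LPS wild-type cells carried a late profile, with Arg1 and glycolytic genes high and proliferation genes very low. Arg1 (arginase 1) rose from 0.0373 ± 0.0186 CPM untreated to 200.1 ± 14.1 CPM (n = 3). Cxcl3 changed by 11.09 ± 0.81, Il1b by 10.96 ± 0.84 and the acute-phase gene Saa3 by 10.20 ± 0.83. Glycolysis genes rose in 16 of 23 cases (median 1.33), including the lactate exporter gene Slc16a3 (3.62 ± 0.54) and the glucose transporter gene Slc2a1 (3.13 ± 0.42). Of 16 hypoxia response genes 11 rose and none fell (median 2.21), among them Egln3 (4.31 ± 0.81) and Bnip3 (3.16 ± 0.58). All 23 G2 and M phase genes fell (median -5.94), with Cenpf at -8.26 ± 0.56 and Plk1 at -7.94 ± 0.56. Among the largest falls were also Troap (-9.29 ± 0.61), Aspm (-9.06 ± 0.48), Pbk (-8.81 ± 1.06) and Pif1 (-8.57 ± 0.54). S phase genes fell in 17 of 22 cases, with Rrm2 at -6.91 ± 1.02. All 21 cholesterol synthesis and uptake genes fell (median -2.01). Mitochondrially encoded mRNAs fell in 9 of 13 cases (median -1.04), with mt-Nd1 at -1.41 ± 0.15. MHC class II genes fell in 6 of 10 cases, with their activator gene Ciita at -2.60 ± 0.34 and H2-Eb1 at -1.88 ± 0.19. Transcripts that mark neutrophils and their precursors fell in 11 of 15 cases (median -4.09), with Ngp at -6.67 ± 0.22 and Ltf at -5.94 ± 0.22. The test called 9963 of 18083 genes, 5033 higher and 4930 lower, and 22 lists. The balance turned with the scaling, from 50.5% of calls higher to 43.9% with upper-quartile scaling. With an estimated correlation the neutrophil markers (adjusted p = 0.00107) and the chemokines (0.00798) kept their call. Adjusted p was 0.56 for glycolysis, 0.524 for hypoxia, 0.097 for G2 and M phase, 0.56 for S phase, 0.097 for cholesterol synthesis, 0.56 for mitochondrial mRNAs and 0.21 for MHC class II. When the fold had to exceed 1.5, 5286 genes were called.

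Between 4 and 24 h of LPS, wild-type cells turned down much of the early inflammatory programme. Il6 fell from 645 to 7.24 ± 9 CPM (n = 3). The pentraxin gene Ptx3 changed by -9.59 ± 0.68, the scavenger receptor gene Olr1 by -8.99 ± 0.58, the metalloreductase gene Steap4 by -8.22 ± 0.82 and Il19 by -8.13 ± 0.67. Of 20 cytokine genes 16 fell and none rose (median -3.78). Of 24 NF-kB regulators 18 fell (median -2.10; Tnfaip3 -4.36 ± 0.40). Of 38 interferon-stimulated genes 28 fell (median -1.31; Ifit1 -3.35 ± 0.41). Rising genes included Arg1 (8.69 ± 0.72), the thrombospondin gene Thbs1 (6.37 ± 0.69), the scavenger receptor gene Marco (5.49 ± 0.90), Slco4a1 (6.49 ± 0.37) and Fam83f (5.88 ± 0.31), while Mnt (6.44 ± 0.25) and Cnr2 (6.42 ± 0.55), among the largest early falls, rose again. All 23 G2 and M phase genes were lower at 24 h than at 4 h (median -4.84). The test called 11139 genes, 5801 higher and 5338 lower at 24 h (52.1% higher, but 48.6% with RLE and 49.1% with upper-quartile scaling), and 6840 when the fold had to exceed 1.5. Of the 11 lists called, only the neutrophil markers kept their call with an estimated correlation (adjusted p = 0.0222). It was 0.514 for the cytokines, 0.444 for the NF-kB regulators, 0.819 for the interferon-stimulated genes and 0.444 for G2 and M phase.

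**Figure D2:**
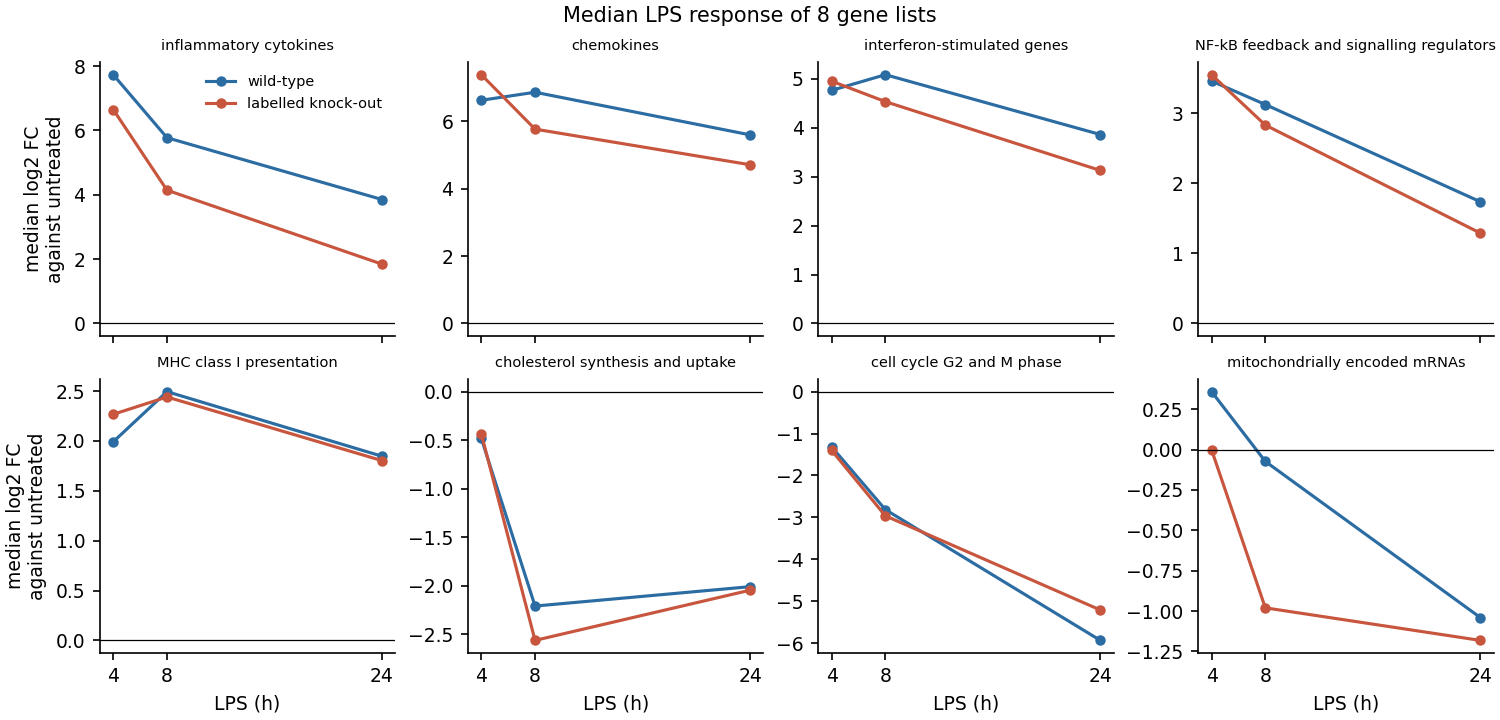
Median log2 fold change against untreated cells (vertical axis) of 8 gene lists at 4, 8 and 24 h of LPS (horizontal axis) in wild-type and labelled knock-out cells; genes without reads in a group enter at their bound. Cytokine genes peak at 4 h (wild-type median 7.73) and G2 and M phase genes are lowest at 24 h (wild-type median -5.94) in both genotypes.

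The labelled knock-out cells answered LPS with largely the same genes. At 4 h all 20 cytokine genes rose (median 7.36, or 6.65 with 3 members without untreated reads at their bound), with Il6 going from 0.265 ± 0.229 to 655 ± 332 CPM (n = 3), Il12b at 11.36 ± 1.84, and Ifnb1, without untreated reads, at least 610.0-fold higher. 20 of 21 chemokine genes, all 38 interferon-stimulated genes and all 24 NF-kB regulators rose (medians 7.39, 4.95 and 3.55), and Zfp395 (-7.59 ± 0.72), Cnr2 (-6.85 ± 0.54) and the sestrin gene Sesn1 (-6.48 ± 0.39) were among the largest falls. At 8 h Saa3 changed by 11.32 ± 0.87 and Ccl5 by 10.19 ± 0.65, and the granulocyte growth factor gene Csf3 was at least 400.0-fold higher. Rasgrp3 (-8.82 ± 0.63) and Slco2b1 (-7.28 ± 0.60) were among the largest falls. All 21 cholesterol synthesis and uptake genes (median -2.56) and 12 of 13 mitochondrially encoded mRNAs (median -0.98) fell at 8 h. At 24 h (n = 2) Arg1 stood at 142 ± 9.81 CPM. Cfb, a complement factor gene, had changed by 8.91 ± 0.40, and all 23 G2 and M phase genes were lower (median -5.21; Cenpf -8.20 ± 0.66), as was the immunoglobulin gene Ighm (-8.46 ± 0.64). From 4 to 24 h 19 of 20 cytokine genes fell (median -3.94). Il19, without reads at 24 h, was at least 658-fold lower, Ptx3 changed by -9.95 ± 0.84 and Arg1 rose by 7.90 ± 0.71. The test called 11223 genes at 4 h (5060 higher, 6163 lower), 10886 at 8 h (5120 and 5766), 7849 at 24 h (4082 and 3767) and 10067 between 4 and 24 h (5339 and 4728). When the fold had to exceed 1.5 these were 7289, 6444, 3763 and 6040. The 24 h count fell to 5015 without libraries 13, 16, 19 and 22 and to 4920 without library 23, and with upper-quartile scaling the median of all genes shifted by -0.11 at that time and the share of calls that were higher went from 52.0% to 42.4%. Between 4 and 24 h that share was 53.0%, but 48.1% with RLE scaling. With an estimated correlation the chemokines kept their call at 4, 8 and 24 h (adjusted p = 0.0323, 0.024 and 0.0319). At 4 h the cytokines had 0.147, the interferon-stimulated genes 0.147 and the NF-kB regulators 0.0652, at 8 h cholesterol synthesis 0.0754 and mitochondrial mRNAs 0.467, at 24 h G2 and M phase 0.0974, and from 4 to 24 h the cytokines 0.341.

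Set side by side, the wild-type and labelled knock-out responses share no library, and their log2 fold changes correlated across the 18083 genes with Pearson's r of 0.952, 0.937 and 0.896 at 4, 8 and 24 h (Spearman's rho 0.938, 0.915 and 0.849). This is a correlation across genes, which are not independent replicates. The slope of the labelled knock-out on the wild-type response was 0.941, 0.886 and 0.827. At 4 h 10025 genes were called in both genotypes, and 10020 of them had the same sign; at 8 h it was 9477 of 9498 and at 24 h 6704 of 6710. Whether a gene's response differed is tested by the interactions below.

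**Figure D3:**
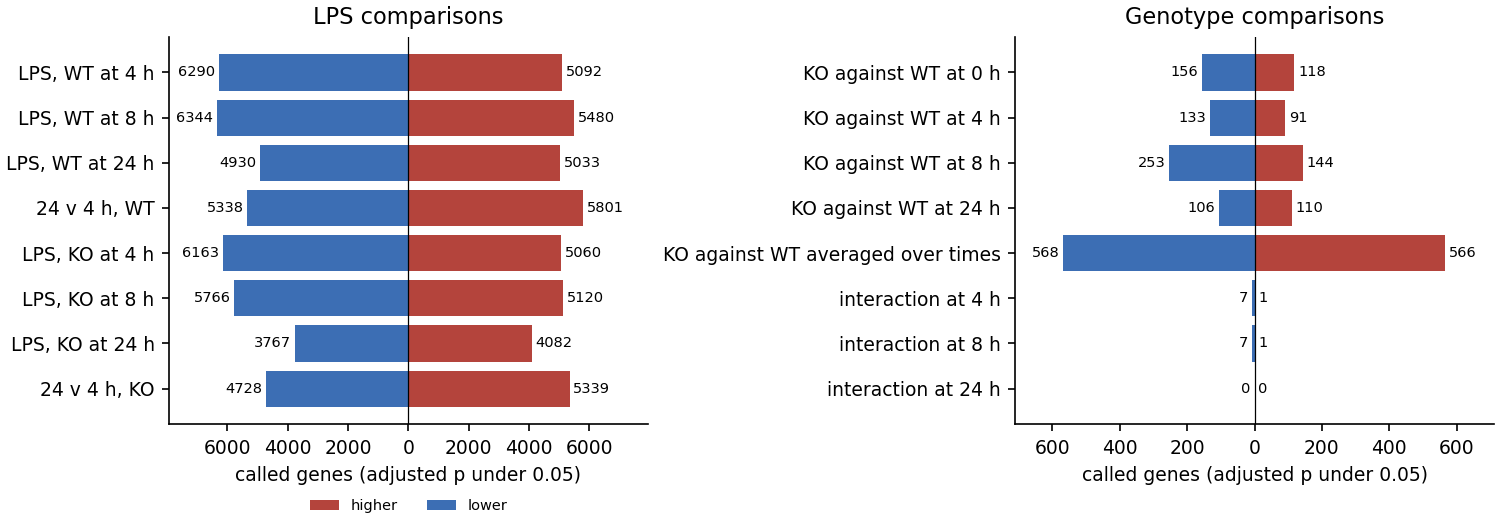
Number of genes called higher (to the right) and lower (to the left) at an adjusted p under 0.05 in each comparison, LPS comparisons in one panel and genotype comparisons in the other, on separate scales. The LPS comparisons call 7849 to 11824 genes and the genotype comparisons up to 1134.

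Before any LPS, labelled knock-out cells differed from wild-type cells in 274 genes, 118 higher and 156 lower (n = 3 per group). Among genes with the largest differences, the growth factor gene Gdf3 (3.24 ± 0.48), the kinase gene Sik1 (4.01 ± 0.41), the glutaminyl cyclase gene Qpct (1.94 ± 0.31), Fkbp9 (1.83 ± 0.19) and AI506816 (6.93 ± 0.54) were higher. The hypoxia-inducible factor gene Epas1 (-3.38 ± 0.25), the tyrosine breakdown gene Fah (-3.43 ± 0.21) and BC002163 (-5.96 ± 0.35) were lower. Rps3a3 (-5.52 ± 0.16), Rps3a2 (-4.66 ± 0.19), Atp6v0c-ps2 (-5.30 ± 0.22), Rpl34 (2.73 ± 0.12) and H2-T10 (-3.22 ± 0.38) belong to families of near-identical copies among which reads can be split, so their changes are uncertain. Neutrophil marker transcripts were higher in 3 of 15 cases (5 adjusted over the list alone; median 0.47), namely S100a8 (1.11 ± 0.24), S100a9 (0.79 ± 0.18) and Ltf (0.77 ± 0.16). None of these 3 genes kept its call without library 1 (adjusted p 0.0887 to 0.114) or library 15 (0.0529 to 0.136). S100a8 and S100a9 also lost it without library 3 or 13 (0.0956 to 0.143) and S100a8 without library 2 (0.054). The macrophage growth factor gene Csf1 was lower (-1.91 ± 0.31, adjusted p 0.00173). Of 4 lists called, only the neutrophil markers kept their call with an estimated correlation (adjusted p = 0.0323). The count was 113 without libraries 13, 16, 19 and 22, 1199 within the first library set, 2467 with the set as a term and 550 with DESeq2. It was 182, 166, 157 and 132 without library 1, 3, 13 and 15, and 101 with only the groups compared, where Csf1 (adjusted p 0.0869), Qpct (0.057) and S100a9 (0.0519) lost their call. Without libraries 13, 16, 19 and 22 S100a8, S100a9 and Ltf lost it (0.0559 to 0.192).

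At 4 h of LPS 224 genes differed between genotypes, 91 higher and 133 lower in labelled knock-out cells. Npy, the neuropeptide Y gene, held 26.7 ± 9.28 CPM against 0.097 ± 0.0487 CPM in wild-type cells (n = 3 per group), and Gdf3 (3.18 ± 0.49), Lrmda (3.20 ± 0.26), Qpct (2.03 ± 0.31), Fkbp9 (1.99 ± 0.19) and AI506816 (6.69 ± 0.53) were higher too. Elavl4, which encodes a neuronal RNA-binding protein, had 13.9 ± 1.51 CPM in wild-type cells and no reads in labelled knock-out cells, at least 473-fold lower. Tagap1, a relative of a T cell activation GTPase-activating protein, stood at 124 ± 17.4 CPM in wild-type and 4.74 ± 0.534 CPM in labelled knock-out cells. The counting ignored strand, so its reads and those of its antisense partner Gm49719 cannot be told apart. Depp1 (-4.55 ± 0.31) and BC002163 (-6.55 ± 0.38) were lower. Neutrophil markers were higher in 3 of 15 cases (4 adjusted over the list alone; Ltf 0.99 ± 0.16), and of the 2 lists called this one kept its call with an estimated correlation (adjusted p = 0.0055). The count was 144 without libraries 13, 16, 19 and 22, 674 within the first library set and 842 with the set as a term.

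At 8 h of LPS 397 genes differed, 144 higher and 253 lower in labelled knock-out cells. Immediate early and handling stress genes were lower in 3 of 17 cases (9 adjusted over the list alone; median -0.74), among them Hspa1a (-1.56 ± 0.20) and Hspa1b (-1.50 ± 0.21), near-identical copies. The cytokine genes Csf2, which encodes granulocyte-macrophage growth factor, and Osm (oncostatin M) were lower (-4.56 ± 0.76, adjusted p 0.00177 and -1.32 ± 0.17, adjusted p 7.4e-05; 2 of 20 on their list, 3 adjusted over the list alone), as was the endosomal ferrireductase gene Steap3 (-2.48 ± 0.36, adjusted p 3.5e-04). Npy (8.62 ± 0.55), Gdf3 (3.72 ± 0.51), the oxysterol-binding protein gene Osbpl3 (3.56 ± 0.48) and Qpct (1.97 ± 0.31) were higher. Elavl4 was at least 266-fold lower, and Ank2 (-4.43 ± 0.57) and Cited4 (-3.57 ± 0.40) were lower. The neutrophil markers Ltf (1.14 ± 0.17) and Ngp (1.07 ± 0.16) were higher. Of 9 lists called, the immediate early genes and the neutrophil markers kept their call with an estimated correlation (adjusted p = 0.0261 for each), and the cytokines did not (adjusted p = 0.906). The count was 179 without libraries 13, 16, 19 and 22, 2650 within the first library set, 2931 with the set as a term and 656 with DESeq2. It was 226, 227 and 254 without library 7, 19 and 21.

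At 24 h of LPS 216 genes differed, 110 higher and 106 lower in labelled knock-out cells. Npy reached 61.1 ± 23.9 CPM (n = 2) against 0.032 ± 0.0278 CPM in wild-type cells (n = 3), Sh3d19 8.9 ± 1.5 against 0.0464 ± 0.0225 CPM, and Gdf3 (3.63 ± 0.51), Lrmda (3.02 ± 0.25) and the mannosidase gene Man2a2 (2.72 ± 0.25) were higher. Epas1 (-3.73 ± 0.32), the lysosomal transporter gene Abca5 (-2.78 ± 0.29) and BC002163 (-5.59 ± 0.41) were lower. Neutrophil marker transcripts were higher in 3 of 15 cases (4 adjusted over the list alone), with Ltf at 2.38 ± 0.23, adjusted p 2.1e-06, Ngp at 2.25 ± 0.23 and S100a9 at 1.33 ± 0.21. Nos2 stood at 374 against 1765 CPM, which did not pass the test (log2 fold change -2.24, adjusted p 0.415) and became 0.23 without library 12 and -4.22 without library 23. It passed with the library set as a term (-2.20, adjusted p 0.00205). It also passed within the first set (-1.76, adjusted p 0.0155), where library 22 is the only labelled knock-out library at this time and the spread comes from other groups. Of 7 lists called, the neutrophil markers kept their call with an estimated correlation (adjusted p = 0.0369). The count was 93 without libraries 13, 16, 19 and 22, 998 within the first library set, 3530 with the set as a term and 431 with DESeq2. It was 122 and 137 without library 22 and 23, and 34 with only the groups compared. In that fit Gdf3 (adjusted p 0.159), Lrmda and BC002163 (0.0506 each), Epas1 (0.0843), Ltf (0.106), Ngp (0.0813) and S100a9 (0.181) lost their call.

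Averaged over the 4 times, 1134 genes differed, 566 higher and 568 lower in labelled knock-out cells. Npy (8.34 ± 0.29, adjusted p 7.1e-14), AI506816 (6.60 ± 0.27), Sh3d19 (5.14 ± 0.20), Gdf3 (3.44 ± 0.25) and Lrmda (3.17 ± 0.13) were higher, and BC002163 (-6.14 ± 0.20), Depp1 (-3.81 ± 0.18) and the microtubule-associated protein gene Map2 (-3.76 ± 0.67) were lower. Steap3 (-1.71 ± 0.18), Csf1 (-0.96 ± 0.16) and Osm (-0.57 ± 0.09) were lower, and the receptor genes Tlr2 (0.42 ± 0.08) and Tnfrsf11a (0.63 ± 0.09) were higher. Neutrophil markers were higher in 6 of 15 cases (6 adjusted over the list alone; median 0.61), among them Ltf (1.32 ± 0.09), Ngp (1.15 ± 0.09), S100a8 (0.78 ± 0.13) and S100a9 (0.77 ± 0.09), and kept their call with an estimated correlation (adjusted p = 0.00504). Fibroblast and stroma markers were higher in 8 of 13 cases (9 adjusted over the list alone; median 2.82), among them Col3a1 (4.76 ± 0.92) and Bgn (3.12 ± 0.63). They lost their call with an estimated correlation (adjusted p = 0.97). Col1a1 had 577, 576, 1492 and 708 reads in libraries 14, 17, 20 and 23 and 21 to 123 in every other library, but Dcn and Lum of the same list had 2 to 135 and 1 to 26 reads in these 4 and 0 to 218 and 0 to 40 in wild-type libraries. Within the first library set Col3a1 changed by 1.96 (adjusted p 0.0297) and Bgn lost its call (adjusted p 0.0546), as it did with limma-voom (0.0893). Csf1, Osm, S100a9 and Tlr2 lost theirs within the second set (0.0652 to 0.094). In 30 genes the labelled knock-out was called higher at each of the 4 times and in 59 lower at each. Calls independent between times would give 2.9e-05 and 9.4e-05 genes, but the labels do not say that libraries of different times are unrelated, and both this figure and the test of the average take them so. Any difference that lasts over the times exceeds this figure, whatever its cause. None of the 653 genes called at any time was called in opposite directions. By chromosome, 205 of 984 tested genes on chromosome 17 were called (20.8%), against 2.63% to 8.87% on the other autosomes, 4.07% on the X chromosome, 18.2% on the Y chromosome (2 of 11) and 6.06% of mitochondrial genes (2 of 33). The count was 591 without libraries 13, 16, 19 and 22, 4321 with the library set as a term, 2440 within the first set and 527 within the second. Of these, 345 genes were called in both sets, all in the same direction. When the fold had to exceed 1.5, 239 genes were called.

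**Figure D4:**
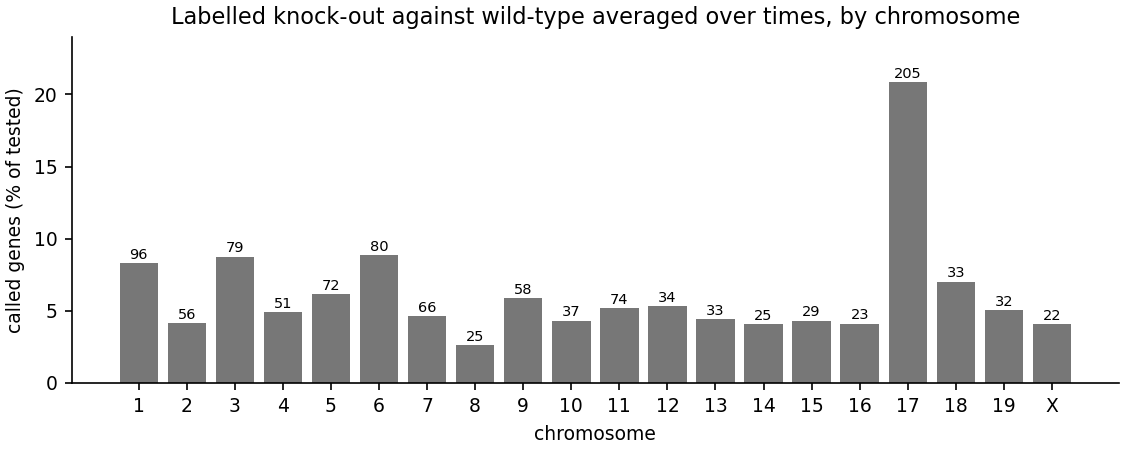
Percent of tested genes called between labelled knock-out and wild-type cells averaged over times (vertical axis), by chromosome (horizontal axis), with the number called above each bar; the Y chromosome and mitochondrial genes are not shown. Chromosome 17 stands at 20.8% and every other chromosome shown at 8.87% or less.

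The interaction at 4 h asks whether the early LPS response differs by genotype, and 8 genes passed the test, 1 higher and 7 lower in the labelled knock-out response. Tagap1 rose in wild-type cells from 10.2 ± 0.412 to 124 ± 17.4 CPM and stood at 6.92 ± 0.218 and 4.74 ± 0.534 CPM in labelled knock-out cells (n = 3 per group; interaction -4.15 ± 0.35, adjusted p 4.8e-06; chromosome 17, 6955011 to 6961156). Its antisense partner Gm49719 was also called (-3.99), and unstranded counting cannot separate the 2 genes. Nlrc4, an inflammasome sensor of bacterial flagellin and secretion systems, rose from 11.5 ± 2.72 to 56 ± 3.76 CPM in wild-type cells and stood at 17.8 ± 3.33 and 9.73 ± 0.344 CPM in labelled knock-out cells (-3.16 ± 0.38, adjusted p 5.7e-04). Cdc42ep3, which encodes an effector of the GTPase Cdc42, fell further in labelled knock-out cells (-2.30 ± 0.32, adjusted p 0.00502), as did Pcyox1, a prenylcysteine oxidase gene (-1.16 ± 0.19, adjusted p 0.022). Asb4 and 2 processed pseudogenes, Gm6548 and Gm7367, made up the 8. Tagap1, Gm49719, Nlrc4, Cdc42ep3 and Gm6548 lie on chromosome 17. The count was 3 without libraries 13, 16, 19 and 22, 68 within the first library set, 158 with the set as a term, 36 with DESeq2 and 4 with only the groups compared. In that last fit Cdc42ep3 and Pcyox1 lost their call (adjusted p 0.0541 each), as they did without libraries 13, 16, 19 and 22 (0.221 and 0.518). It was 4 or 5 without library 2, 3, 4, 5, 6, 13, 15 or 16. Pcyox1 lost its call without any of these or library 18 (adjusted p 0.0515 to 0.112).

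At 8 h 8 genes again passed the interaction test, 1 higher and 7 lower. Nlrc4 reached 102 ± 11.5 CPM in wild-type and 35.7 ± 7.65 CPM in labelled knock-out cells (interaction -2.15 ± 0.37, adjusted p 0.0402). The MAP kinase phosphatase gene Dusp10 stood at 17.1 ± 3.39 and 5.49 ± 0.163 CPM (-1.52 ± 0.26, adjusted p 0.0402), and the single-stranded DNA-binding protein gene Nabp1 at 59.6 ± 10.9 and 30.9 ± 3.33 CPM (-1.18 ± 0.18, adjusted p 0.0128). Abca5 (-2.55 ± 0.37, adjusted p 0.0128), the antiproliferative gene Tob1 (-1.23 ± 0.21, adjusted p 0.0402), the phosphatase regulator gene Ppp1r10 (-0.68 ± 0.12, adjusted p 0.0439) and Asb4 made up the genes lower in the labelled knock-out response, and the tyrosine kinase gene Fes was higher (1.05 ± 0.16, adjusted p 0.0128). Mitochondrially encoded mRNAs had a median interaction of -0.38, -0.61 and -0.49 at 4, 8 and 24 h. No member passed the test over all genes at these times, 8 of 13 passed at 8 h adjusted over the list alone, and the list was called by camera (adjusted p 7.6e-10 at 8 h) but not with an estimated correlation (adjusted p = 0.52). The count of genes at 8 h was 0 without libraries 13, 16, 19 and 22, 1667 within the first library set, 2302 with the set as a term, 196 with DESeq2 and 0 with only the groups compared. It was 0 without library 1, 2, 7 or 20, so no gene kept its call in all of these fits, 2 to 5 without library 4, 13, 15, 16, 18, 19, 21, 22 or 23, and 20 without library 12. Abca5 and Dusp10 lost their call with limma-voom (adjusted p 0.0738 and 0.0626), Ppp1r10 with RLE scaling (0.0673), and Ppp1r10 and Tob1 without a filter (0.219 and 0.0654).

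At 24 h no gene passed the interaction test in edgeR, where 1835 genes had an unadjusted p under 0.05. DESeq2 called 128 genes, limma-voom 2 and the fit of only the groups compared 1, the fit within the first library set, with 1 labelled knock-out library at 24 h, 787 and the fit with the set as a term 2957. The count was 1 to 5 without library 3, 4, 7, 8, 9, 11, 12, 14, 17, 18 or 23. The joint test of the 3 interactions called 20 genes. Besides those named above and Sh3d19, which went from 3.74 to 0.661 and 8.9 CPM at 0, 4 and 24 h in labelled knock-out cells (adjusted p 2.2e-04), these were Hspa1a and Hspa1b, Gm20481, Gm5879 and Ubald2. The joint count was 3 without libraries 13, 16, 19 and 22, 31 without library 17, 261 with DESeq2, 1814 within the first library set and 3526 with the set as a term.

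**Figure D5:**
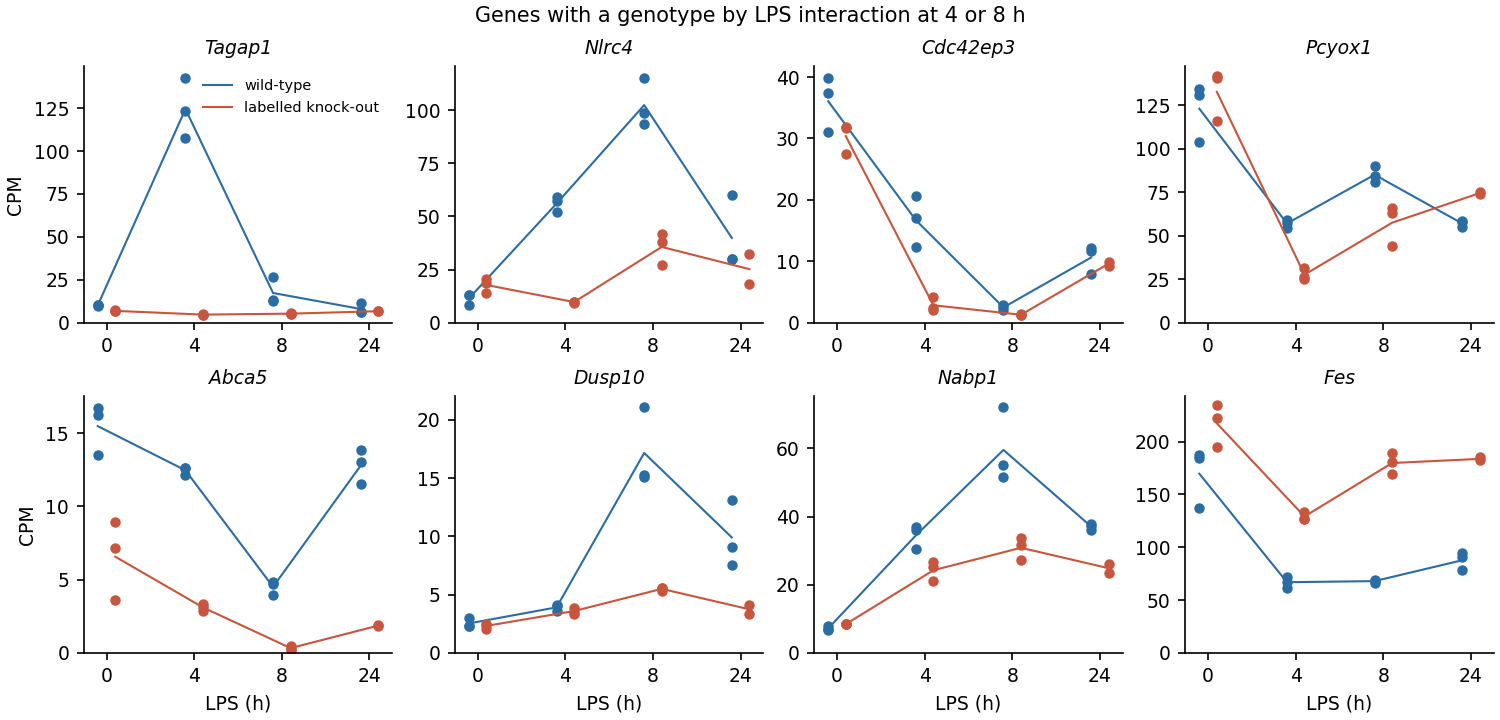
CPM (vertical axes, separate scales) of 8 genes called for an interaction at 4 or 8 h, by hours of LPS (horizontal axes, not to scale); points are libraries and lines join group means. Tagap1 stands at 124 CPM in wild-type and 4.74 CPM in labelled knock-out cells at 4 h, and Nlrc4 at 102 and 35.7 CPM at 8 h.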

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

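Chosen only after the result was seen were the tests of Selenow, of neighbouring genes, of the genes called lower, of the library sets and of splits of 3 against 3 libraries, as well as every fit that uses the library sets or leaves out libraries 13, 16, 19 and 22. Tests of the genome around Selenow, of marker lists and of splits of the average and the interactions were chosen before their results.

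A test of the difference itself, the interaction of genotype and LPS, called genes for an LPS response that differs between genotypes: 8 at 4 h, 8 at 8 h and 20 in the joint test of all times. At 4 h the log2 interactions were -4.15 for Tagap1, -3.16 for Nlrc4, -2.30 for Cdc42ep3 and -1.16 for Pcyox1. At 8 h they were 1.05 for Fes, -2.55 for Abca5, -2.15 for Nlrc4, -1.52 for Dusp10, -1.23 for Tob1, -1.18 for Nabp1 and -0.68 for Ppp1r10. Of 100 splits that exchange genotype labels within times, 13 gave at least 8 genes at 4 h (highest other 941) and 10 gave at least 8 at 8 h (highest other 502). Splits with many times the real count point to a structure of the samples. Part of it is the genotype difference itself: exchanging every label at 1 time and none at the other turns a constant difference between genotypes into an interaction, and such splits gave 548 genes at 4 h and 502 at 8 h. Splits of this kind, in whole or in part, are no measure of chance, which is left open for these counts. With the library set as a term, the real counts were 158 and 2302. At 4 h 6 of 72 splits were as large, the largest other with every label at 4 h exchanged (3039), and at 8 h 2 of 72, the real split and 1 with every label at 8 h exchanged (2709). Chance is left open here for the same reason, though the rule set beforehand was met at 4 h and not at 8 h.

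Selenow stood near the wild-type level in libraries 13, 16, 19 and 22. A swap with libraries labelled wild-type would leave low Selenow in some of those, but the lowest held 85.3% of the wild-type mean of its time, which argues against it. Wild-type RNA or cells mixed in are also argued against: Elavl4 and 2 predicted loci, at 0 in the other labelled knock-out libraries and at 20 to 701 counts in each wild-type library, had 0 reads in all 4 libraries, which allows a share of at most 0.720%, where Selenow would need 70.1% to 106%. The 4 libraries also lay nearer the other labelled knock-out libraries over genes that differ between the groups (medians 0.803 to 0.946 of the way). Those genes were called in fits that held the rest of the 4. A candidate explanation left open, and not tested, is animals of the knock-out colony that still carried an intact Selenow gene, so the comparisons by label mix levels of Selenow.

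For the 1134 genes called between genotypes on average, 1 of 100 splits, the real one, was as large (highest other 8), but a labelled knock-out library with near wild-type Selenow, and the library sets, recur at each time, and if libraries of different times are related, moving them together would give 10 splits, too few for a share under 0.05. Genome carried along with the targeted locus is argued against as the whole cause, since 1120 of the calls remain without genes within 20 Mb of Selenow, where 2.92% of tested genes were called against 6.36% elsewhere (odds ratio 0.442, 95% interval 0.239 to 0.753, Fisher's exact test, two-sided p = 0.0011). That test takes genes as independent, while calls cluster along the genome, so its p-value can be too small and its interval too narrow. Cells of another type in the cultures may add to the higher genes: the neutrophil list (median 0.61) kept its call with an estimated correlation (adjusted p 0.00504), while the fibroblast list moved most (median 2.82) but lost it (adjusted p 0.97) and was mixed, with Col1a1 at 576 to 1492 reads in libraries 14, 17, 20 and 23 and 21 to 123 in the others, and Dcn at 2 to 135 in these 4 and 0 to 218 in wild-type libraries. That 20 of the 1134 genes are on a marker list cannot decide this, since the lists are short and could hold only few of the calls. Against such cells as the whole cause, macrophage identity genes did not fall (median 0.15, quartiles 0.00 to 0.23). Dilution by other cells would have to match the 568 genes called lower (median -0.74, quartiles -1.45 to -0.43, a foreign share of 40.3%). Stretches of genome that differ between the colonies are a candidate explanation. These data do not separate them from the genotype (the loss of Selenow or other differences between the colonies), which stays open as well. In an order of 13691 genes that do not overlap, on the autosomes and X, 899 of the called genes were neighbours 167 times. That was 2.83 times the mean of 58.9 over 10000 permutations (highest 85, p = 1e-04, the smallest they can give). For the 1134 strongest genes of the 4 h response in wild-type cells, 900 of them in that order, it was 1.63 times. For most genes called with at least a 2-fold difference, a low Selenow transcript level is argued against by 4 libraries with near wild-type Selenow. Libraries 13, 16, 19 and 22 lay 0.803 to 0.946 of the way to the other labelled knock-outs (medians), and no wild-type library exceeded 0.17. These genes came from fits that held the rest of the 4, so genes that follow Selenow were less likely to be among them. In libraries 13, 16, 19 and 22, 82.8%, 78.2%, 78.1% and 67.5% of them lay nearer the labelled knock-out, the lowest share of each group. Genes that follow Selenow can be among the rest. Smaller differences are not covered, and whether the transcripts are intact is unknown, so loss of intact Selenow stays open.

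Libraries 3, 6, 9, 12, 14, 17, 20 and 23 deviated from their group means in a shared way. A difference in library size is argued against, since both libraries of this kind lay on the same side of the others in total counts at 1 of 4 times, and so is a difference in sex, since the Y-linked gene Ddx3y stood at 26.6 to 61.3 CPM in all 23 libraries and in these 8 at no less than 78.3% of the mean of the others of their group. A batch of cultures or libraries shared by both genotypes is consistent with the correlation of deviations between genotypes, at least 0.755 at every time on chromosomes not used to find the libraries, although at 24 h the sign in the labelled knock-out is fixed by having 2 libraries. At every time the pair was picked as the most correlated one on the odd-numbered chromosomes of the same libraries. A positive value on the even-numbered ones was thereby favoured, so it is no independent check. No label names such a batch, and differences between animals (age, litter) stay open and untested. Each group holds 1 such library, which is 1 of 2 in the labelled knock-out at 24 h and 1 of 3 in every other group, so the sets are unbalanced at 24 h.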

How the results depend on the processing

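Chosen after seeing the data were the fits without libraries 13, 16, 19 and 22, with the library set as a term, and within either set, so these are not independent of the data. Selenow itself was not tested without those 4 libraries, since its level chose them. No label pairs libraries between groups, and no paired analysis was run. The only block fitted was the library set, found in the data. Libraries of different times were taken as unrelated, which the labels do not state. Near wild-type Selenow recurs in the first-numbered labelled knock-out library of every time (13, 16, 19 and 22). The next-numbered ones (14, 17, 20 and 23) and the last-numbered wild-type ones (3, 6, 9 and 12) form the second library set. Both recurrences speak for series that run through the times. Not every pair of deviations did (3 with 12 correlated at 0.04, 16 with 19 at -0.02). If times are related, the fit takes related libraries as independent. P-values of the average over times can then be too small, and those of LPS responses and interactions can be off as well. Unless a value shows it, the cause was not tested for the changes below.

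With limma-voom, RLE or upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, or without genes within 20 Mb of Selenow, the number of called genes stayed within 1.5 times that of the analysis reported, except for the interaction at 24 h (0 reported), which gave 2 with limma-voom, 1 with RLE scaling, 8 without a filter and 3 with 1 CPM. LPS counts kept within 1.5 times under every alternative but 3. The fold of 1.5, which by construction asks for more, gave 7384, 7509 and 5286 at 4, 8 and 24 h and 6840 for 24 against 4 h in wild-type cells, and 7289, 6444, 3763 and 6040 in labelled knock-out cells. Without libraries 13, 16, 19 and 22 the labelled knock-out at 24 h, then with 1 library assumed to vary like the other groups, gave 5015, and without library 23 alone 4920. With RLE scaling the share of calls that were higher also turned for the labelled knock-out at 8 h (47.0% to 50.3%) and between genotypes at 24 h (50.9% to 48.8%).

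Between genotypes the counts at 0, 4, 8 and 24 h and on average (274, 224, 397, 216 and 1134 reported) were 102, 123, 160, 108 and 239 for the fold of 1.5, and 5 and 1 for the interactions at 4 and 8 h (8 each reported). DESeq2 gave 550 at 0 h, 656 at 8 h and 431 at 24 h, and 36, 196 and 128 for the interactions at 4, 8 and 24 h and 261 for the joint test (20 reported). With only the groups compared, which leaves fewer libraries to estimate the spread, counts were 101 at 0 h, 34 at 24 h, and 4, 0 and 1 for the interactions at 4, 8 and 24 h. At an adjusted p under 0.01 they were 131 at 0 h, 219 at 8 h, 133 at 24 h, 574 on average, 4 and 0 for the interactions at 4 and 8 h and 7 for the joint test. Without libraries 13, 16, 19 and 22 they were 113, 144, 179, 93 and 591, with 3 and 0 for the interactions at 4 and 8 h and 3 for the joint test. The library set as a term gave 2467, 842, 2931, 3530 and 4321, with 158, 2302 and 2957 for the interactions and 3526 for the joint test. Within the first set they were 1199, 674, 2650, 998 and 2440, with 68, 1667, 787 and 1814, and within the second set 527 on average. The cause of the higher counts with the sets was not tested, and p-values that use sets found in the data can be too small.

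Leaving out each library in turn gave, for LPS in wild-type cells, 10340 to 11525 genes at 4 h, 10809 to 11950 at 8 h, 8623 to 10119 at 24 h and 10180 to 11275 for 24 against 4 h. In labelled knock-out cells it gave 10249 to 11398, 9896 to 11094, 4920 to 8182 and 8157 to 10290. Between genotypes it gave 132 to 316 at 0 h, 176 to 243 at 4 h, 226 to 500 at 8 h, 122 to 282 at 24 h and 829 to 1171 on average. The interactions gave 4 to 9, 0 to 20 and 0 to 5 genes at 4, 8 and 24 h and 14 to 31 in the joint test. Selenow ranged from -1.59 to -0.72 at 0 h, -1.25 to -0.51 at 4 h, -1.29 to -0.68 at 8 h, -0.65 to 0.03 at 24 h and -0.86 to -0.63 on average. It passed the test at 0 h without library 13 (adjusted p 0.0326) and changed sign at 24 h without library 23 (0.029), which leaves library 22 alone. Within the first set, where 4 of the 7 labelled knock-out libraries are 13, 16, 19 and 22, a smaller Selenow difference is built in. It was 0.12 at 24 h, where library 22 stands alone (sign reversed, adjusted p 0.942), and -0.43 on average, no longer called (adjusted p 0.202, against 0.00566 to 0.0325 under the alternatives that keep all libraries). Nos2 between genotypes at 24 h ranged from -4.22 without library 23 to 0.23 without library 12, where its sign changed.

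Of 42 gene lists, camera with an estimated correlation called 1, 3, 2 and 1 for LPS at 4, 8 and 24 h and 24 against 4 h in wild-type cells (8, 16, 22 and 11 reported), and 1, 2, 2 and 1 in labelled knock-out cells (10, 17, 23 and 10 reported). It called 1, 1, 2, 1 and 1 between genotypes at 0, 4, 8 and 24 h and on average (4, 2, 9, 7 and 2 reported), and 0, 0 and 0 for the interactions (4, 3 and 6 reported). Fry, which asks a different question, called 25, 34, 35 and 31 in wild-type cells, 27 and 34 at 4 and 8 h and 29 for 24 against 4 h in labelled knock-out cells, 1, 1, 2, 3 and 4 between genotypes, and 0, 0 and 0 for the interactions. With 1 CPM in 3 libraries 1 list was called between genotypes at 4 h and 4 at 24 h. Of 672 results of a list in a comparison, 135 lost their call with an estimated correlation and 32 with fry, which added 131. With 1 CPM in 3 libraries 15 of 624 lost it and 1 gained it. No list called in both reversed with fry or that filter. The fit with an estimated correlation was given the direction of the main result, so it could not show a reversal.

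Of 197 results of a named gene in a comparison, 1 lost its call with DESeq2, 4 with limma-voom, 1 with RLE scaling, 2 without a filter, 21 for the fold of 1.5, 13 at an adjusted p under 0.01, 14 without libraries 13, 16, 19 and 22, 1 within the first set and 0 with upper-quartile scaling, 1 CPM in 3 libraries or the set as a term. It was 19 of 176 with only the groups compared and 6 of 21 within the second set. Nos2 between genotypes at 24 h gained a call with the set as a term and within the first set, there with 1 labelled knock-out library. Leaving out each library in turn cost 14 of the 197 results their call at least once, 7 of them interactions at 8 h. Because some genes were left out of the text for this reason, the same count over all 219 results that the naming rule gives for the largest changes is 14. Over those 219 results, 3 lost their call with DESeq2, 6 with limma-voom and 2 within the first set.

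In counts simulated from these libraries, the test recovered 26.5%, 61.1% and 96.8% of changes of 1.5, 2 and 4-fold for LPS in wild-type cells at 4 h (17195 genes), 25.4%, 71.2% and 90.7% between genotypes at 0 h (17828 genes), 74.1%, 97.3% and 95.7% on average (17830 genes), and 5.17%, 43.2% and 83.8% for the interaction at 4 h (17827 genes). False calls numbered 4, 8, 8 and 1. Genes were drawn independently, without library sets and with few changed, so recovery in the real libraries can differ.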

Other observations

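Splits of 3 against 3 libraries, and every fit with the library sets or without libraries 13, 16, 19 and 22, were chosen as tests after the results were seen. Selenoprotein genes other than Selenow also responded to LPS. In wild-type cells at 8 h, Txnrd1, a thioredoxin reductase gene, rose by 1.91 ± 0.18 in log2 fold change (± SE), while Gpx1 (-1.74 ± 0.12), Selenoh (-2.29 ± 0.42) and Txnrd3 (-2.68 ± 0.33) fell. At 24 h Selenop (-3.56 ± 0.79), Selenoh (-3.27 ± 0.44) and Gpx3 (-2.02 ± 0.57) were low and Selenos (0.84 ± 0.13) was high. Of 20 selenoprotein genes 4 were called higher and 8 lower at 24 h, and the list was not called by camera (adjusted p 0.494). In labelled knock-out cells at 24 h Selenop (-3.44 ± 0.93), Selenoh (-2.42 ± 0.50) and Gpx3 (-2.17 ± 0.66) fell too. Between genotypes on average, Selenoi (-0.37 ± 0.08) and Dio2 (-0.76 ± 0.22) were called lower besides Selenow. Selenop and Gpx3 lost their call in labelled knock-out cells without library 23 (adjusted p 0.0891 and 0.13), Gpx3 also without libraries 13, 16, 19 and 22 (0.0814). Selenoi lost its call within the second library set (0.145). Dio2 lost its call there (0.141), with limma-voom (0.0746), without libraries 13, 16, 19 and 22 (0.0725) and without any 1 of 17 of the 23 libraries (0.0504 to 0.112).

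At 24 h 13 of 22 genes of the unfolded protein and integrated stress response were called higher in wild-type cells (median 0.68), with Ddit3 at 3.25 ± 0.20 and Trib3 at 2.33 ± 0.37, and 17 in labelled knock-out cells (median 1.14). Camera called the list in both, with adjusted p of 0.00978 and 4.5e-06, but not with an estimated correlation (0.56 and 0.259). Prostaglandin and leukotriene genes went both ways in wild-type cells at 8 h: Ptgs2 rose by 9.54 ± 0.94 in log2 fold change, while Hpgd, which breaks prostaglandins down, changed by -5.19 ± 0.50 and Alox5 by -3.73 ± 0.42. Of 19 genes of that list 8 were called higher and 9 lower, and camera did not call it (adjusted p 0.682). The master regulator gene of lysosomes, Tfeb, changed by -5.46 ± 0.27 at 4 h, when 4 of 25 lysosome genes were called higher and 8 lower (adjusted p 0.43 by camera). Iron handling genes at 8 h included the siderophore-binding protein gene Lcn2 (5.61 ± 0.42) and the ferroxidase gene Cp (5.42 ± 0.49), both higher. Of 14 such genes 9 were called higher and 4 lower, with an adjusted p of 0.0228 by camera and 0.199 with an estimated correlation.

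Comparisons of 3 against 3 libraries give 10 splits, too few for a share under 0.05. The real split was the 1 largest in each. For LPS in wild-type cells the real counts and the highest others were 11382 and 1 at 4 h, 11824 and 0 at 8 h, 9963 and 0 at 24 h, and 11139 and 0 for 24 against 4 h. For labelled knock-out cells they were 11223 and 0 at 4 h and 10886 and 0 at 8 h. Between genotypes they were 274 and 0 at 0 h, 224 and 1 at 4 h, and 397 and 209 at 8 h. The split with 209 genes set libraries 8, 19 and 21 against 7, 9 and 20, with both libraries of the second set on one side, and the fit with the set as a term called 2931 for the real split. The average over times with the set as a term called 4321 genes, where 1 of 100 splits, the real one, was as large (highest other 1652). These splits take libraries of different times as unrelated, and if they are related, moving them together would give 10 splits, too few for a share under 0.05.

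Every gene called between genotypes or for an interaction without the set term was also called with it, for example 1134 of 1134 for the average. The sets were chosen for shared deviations, so their term takes out spread, and this overlap is no separate check. Of 2440 genes called on average within the first library set, 2429 were tested in the second and 94.0% of these changed in the same direction there, against 67.4% of genes not called.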
